A study of Mus musculus with 28 samples.

How the data were processed

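RNA from the lateral ventricle choroid plexus of 28 male mice was sequenced, 1 library per mouse, in 7 groups of 4. Per the labels, mice were anaesthetised and perfused with buffered saline, and the dissected choroid plexus was snap frozen. Poly(A) RNA was made into stranded libraries (TruSeq Stranded mRNA) and sequenced on an Illumina NovaSeq. The processing notes of the authors name FastQC 0.11.8, cutadapt, HISAT2 2.2.1, Picard 2.18.2, featureCounts 2.0.1, DESeq2 and the mouse build mm10. The strand setting, the handling of reads with several alignments, the gene annotation and the versions of cutadapt and DESeq2 are not given in the sources used here. The deposited values are raw counts per Entrez gene, without normalization, in 2 tables: 12 young libraries of batch 1 and 16 aged libraries of batch 2. All 28 columns were used. Replicate numbers name separate mice and follow the order of the sample records, so no animals were paired.

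Entrez identifiers were matched to gene symbols and positions with the RefSeq table of GRCm38.p6, the assembly that mm10 names. Of 27179 identifiers, 25275 (93.0%) matched, and the rest kept their number. Total counts per library ran from 14.6M to 43.9M.

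Genes with enough counts were kept with edgeR's filterByExpr by group. Library sizes were scaled with the trimmed mean of M values (TMM), and a quasi-likelihood model with 1 coefficient per group was fitted in edgeR 4.0.16 (robust glmQLFit, glmQLFTest) under R 4.3.3. Young comparisons were fitted on the 12 young libraries, aged comparisons on the 16 aged libraries, and comparisons across age on all 28. P-values were adjusted by Benjamini-Hochberg over the genes tested in a comparison, with a threshold of 0.05. Standard errors (SE) are the log2 fold change divided by the square root of the F statistic. Levels are CPM, counts scaled by library size, and log2 CPM has a prior count of 2.

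Before the data were examined, 34 gene lists were fixed, 11 of them markers of cell types and 23 of processes. They cover the core clock, ion and water transport into cerebrospinal fluid (CSF), proteins secreted into CSF, solute and hormone carriers, junctions, handling of amyloid-beta, glucocorticoid response, immediate early genes, endoplasmic reticulum (ER) folding and the unfolded protein response, cytosolic heat shock, interferon response, inflammatory cytokines and NF-kB, antigen presentation and complement. Further lists are nuclear and mitochondrial genes of respiration, cytosolic ribosome, cholesterol synthesis, lipid oxidation, autophagy and lysosome, oxidative stress (Nrf2), motile cilia and the cell cycle. Marker lists name choroid epithelium, neuron, oligodendrocyte, astrocyte, ependyma, macrophage, lymphocyte and neutrophil, endothelium, fibroblast, mural and erythroid cells. Of 882 members written, 880 matched a gene, and 42 genes are in more than 1 list. Each list with at least 5 tested members was compared with all other genes by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Counts of members are also given adjusted over the list alone. These counts are not set against the share of all genes that differ, so alone they do not set a list apart. A marker score is the mean log2 CPM of a list's genes. The neural score joins neuron, oligodendrocyte and astrocyte markers, and the stromal score joins endothelium, fibroblast and mural markers. The GC trend of a library is how its log2 counts, against the mean of the libraries, change with the GC content of transcripts. Scores were compared between groups by exact 2-sided permutation tests, adjusted over 120 tests.

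Named genes follow a rule fixed with the lists. In each comparison these are up to 10 genes with the highest and 10 with the lowest log2 fold change among called genes with a mean log2 CPM of at least 1 and a gene symbol that is not a placeholder. Except across age and in interactions, every library of 1 group had to lie above every library of the other. Core clock members are named in day-night comparisons, the members with the smallest p in each list described, App and Zbtb20 in genotype comparisons, every gene where at most 5 were called, and the 3 genes with the smallest p where none was. Some genes that the rule picks are not reported here, though counts include them.

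Alternatives fixed before the data were examined were relative log expression (RLE) and upper-quartile scaling, DESeq2 1.42.0, limma-voom with quality weights, no filter, a filter of at least 10 CPM in 4 libraries, the neural or the stromal score as a covariate, a fit on the compared groups alone, and leaving out each library. Chosen after seeing the data were a correction for GC content by a loess curve (span 0.3), surrogate variables from sva 3.50.0, and leaving out J20+ day library 1 and J20+ night library 2 together. The steps were also tested on simulated data. Counts were drawn for each gene independently from a negative binomial with the mean rate, dispersion and library sizes of the real data. In these, 200 genes were changed by known folds and the ER folding list was shifted by 0.4 on the log2 scale. Differences between libraries that many genes share were not simulated. No library shared its counts with another. Human transgene reads were not analysed here, since the counts are of mouse genes.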

Results

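Gene expression in the lateral ventricle choroid plexus, the epithelial tissue that secretes cerebrospinal fluid, was measured by poly(A) RNA sequencing in 28 male mice. Wild-type mice of 3 to 4 months (young) were sampled at zeitgeber time (ZT) 6, which is 6 h after lights on (day), at ZT 18, which is 6 h after lights off (night), or at ZT 6 after 6 h of sleep disruption. Mice of 12 to 14 months (aged) were J20-positive (J20+) or their wild-type littermates, sampled at day or night. J20 mice carry a human amyloid precursor protein (APP) transgene with mutations of familial Alzheimer's disease. Each of the 7 groups held 4 mice. The young libraries formed batch 1 and the aged libraries batch 2. Total counts were 22.5M to 28.2M in young day, 22.6M to 28.2M in young sleep-disrupted and 24.4M to 28.98M in young night libraries. They were 15.1M to 20.5M in aged wild-type day, 14.6M to 18.4M in aged wild-type night, 19.6M to 43.9M in J20+ day and 15.5M to 30.9M in J20+ night libraries. Over both times, J20+ libraries were deeper than aged wild-type libraries, with means of 26.4M and 16.8M (n = 8 and 8, exact permutation p = 0.00311, adjusted p = 0.343).

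Markers of choroid epithelium were high in every library, with group means of 9.30 to 9.97 log2 CPM. Markers of brain tissue varied among the aged libraries. The neural score, the mean of neuron, oligodendrocyte and astrocyte markers, was 5.50 ± 1.22 log2 CPM (SD, n = 4) in aged wild-type night libraries and 2.78 ± 1.49 in aged wild-type day libraries. In J20+ libraries it was 3.07 ± 1.83 at day and 2.57 ± 1.53 at night, and in the young groups its means were 2.170 to 2.183. Genes were filtered and scaled separately for young and aged libraries, so levels are not compared between the ages. The difference between aged wild-type night and day had an exact permutation p of 0.0571 (adjusted p = 0.343). Over all genes, the first principal component, the main axis of variation, held 70.3% of the variance of aged libraries (n = 16). Its r was -0.971 with the neural score, 0.949 with choroid epithelium markers, -0.879 with the GC trend and 0.605 with total counts. Among young libraries (n = 12) it held 42.3%, with an r of -0.815 with the neural score and 0.936 with the GC trend.

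**Figure D1:**
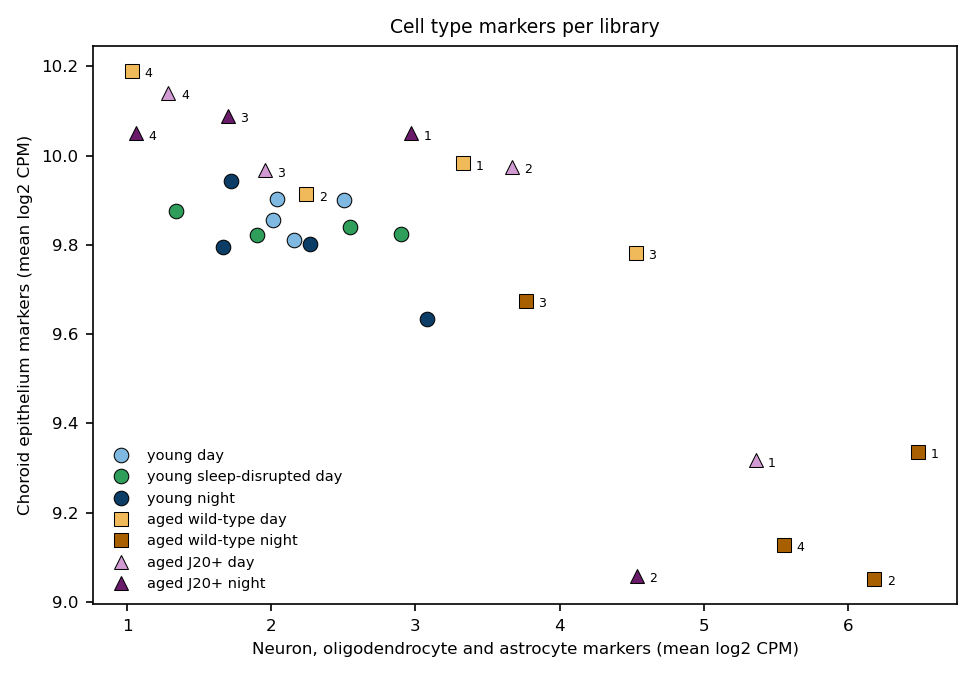
Each point is 1 library, placed by its mean log2 CPM of neuron, oligodendrocyte and astrocyte markers (x axis) and of choroid epithelium markers (y axis), with colour for the group and, beside aged libraries, the replicate number. The aged wild-type night libraries have a mean of 5.50 on the x axis and 9.30 on the y axis, against 2.78 and 9.97 for aged wild-type day libraries. Young and aged libraries were filtered and scaled separately.

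Young night was compared with young day to find genes that differ with time of day. The clearest difference lay in the molecular clock. Arntl (Bmal1), the activator at its core, rose at night by 2.50 ± 0.18 on the log2 scale (SE, n = 4 per group), which is 5.67-fold (Entrez 11865, GRCm38.p6 chromosome 7, 113178471 to 113314126, adjusted p = 4.47e-05). Nr1d1 (Rev-erb alpha), the nuclear receptor that represses Arntl, fell by 3.02 ± 0.24, which is 8.10-fold lower (Entrez 217166, chromosome 11, 98767932 to 98775377, adjusted p = 8.59e-05). Genes of protein folding in the ER also rose at night. Manf, a secreted ER stress protein with neurotrophic activity, rose by 0.87 ± 0.08 (Entrez 74840, chromosome 9, 106888753 to 106891938, adjusted p = 2.10e-04).

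Of 14983 genes tested, 40 were called, 21 higher and 19 lower at night. Among the 24 core clock genes, 5 rose and 5 fell, 14 did not pass, and adjusted over the list alone 5 rose and 8 fell. Besides Arntl, the repressor gene Nfil3 rose by 1.70 ± 0.16, the clock repressor gene Cry1 by 1.17 ± 0.09 and the Clock paralog Npas2 by 0.76 ± 0.12. Besides Nr1d1, the repressor genes Ciart (-1.98 ± 0.35) and Bhlhe41 (-1.25 ± 0.15), Nr1d2 (Rev-erb beta, -1.68 ± 0.16) and Per3 (-0.87 ± 0.14) fell. Members that did not pass included Dbp at -1.68 ± 0.39 (adjusted p = 0.131), Per2 at 0.37 ± 0.18 (0.562) and Per1 at 0.17 ± 0.29 (0.862). As clock genes changed both ways, the list as a whole had no direction (camera adjusted p = 0.719), while fry's test for change either way gave an adjusted p of 5.35e-10.

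**Figure D2:**
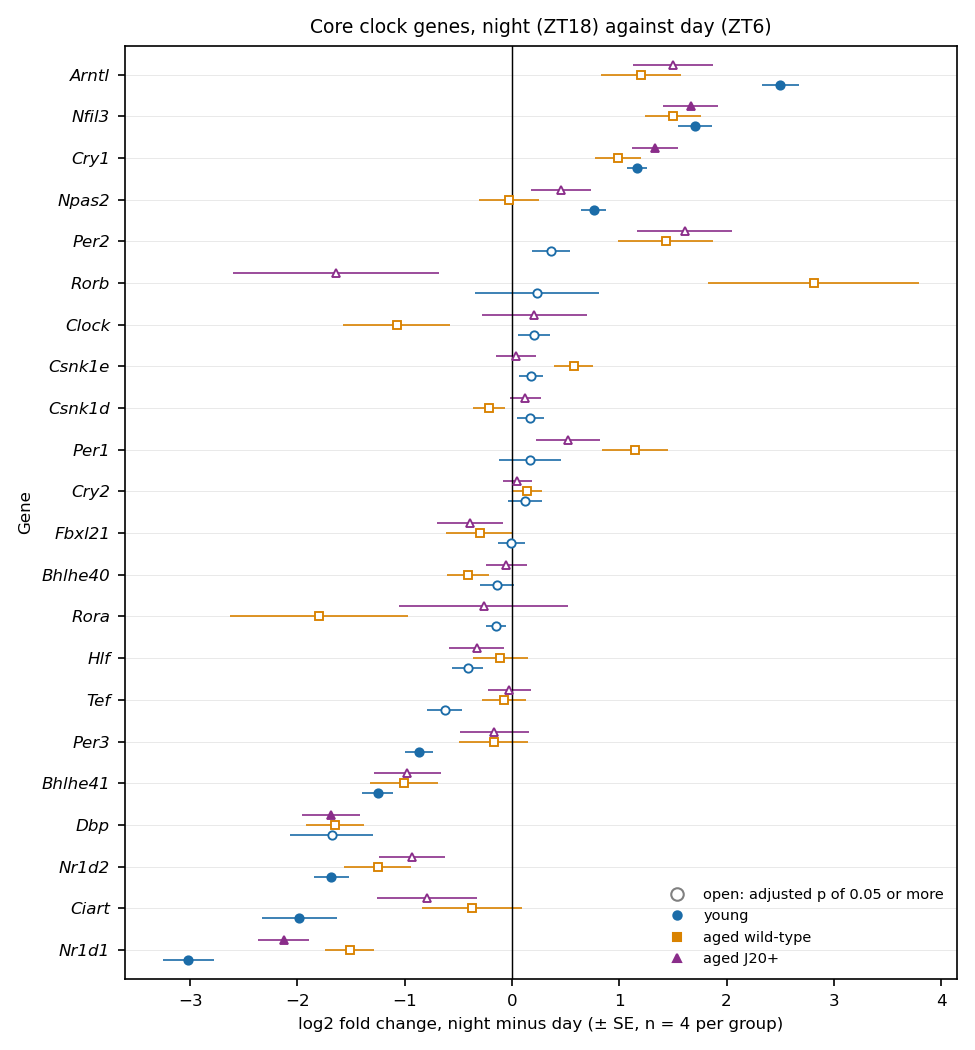
Log2 fold change of core clock genes at night against day (x axis, bars are ± SE, n = 4 mice per group) in young, aged wild-type and aged J20+ mice, with filled symbols for an adjusted p under 0.05. Arntl lies at 2.50, 1.20 and 1.501 in the 3 sets of mice, and Nr1d1 at -3.02, -1.51 and -2.13.

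The ER folding and unfolded protein response list was higher at night as a group (29 genes tested, 27 with positive values, median 0.35, camera adjusted p = 4.90e-16). This list also passed with an estimated correlation (adjusted p = 0.00641) and by fry (3.91e-05). Of its members 7 rose, none fell, 22 did not pass, and adjusted over the list alone 14 rose. With Manf, these were the ER chaperone genes Hyou1 (0.89 ± 0.13) and Hspa5 (BiP, 0.65 ± 0.12), the ER stress transcription factor Xbp1 (0.80 ± 0.09), Sdf2l1 (0.84 ± 0.11), Creld2 (0.94 ± 0.13) and Sel1l, an adaptor of ER-associated degradation (0.35 ± 0.06).

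**Figure D3:**
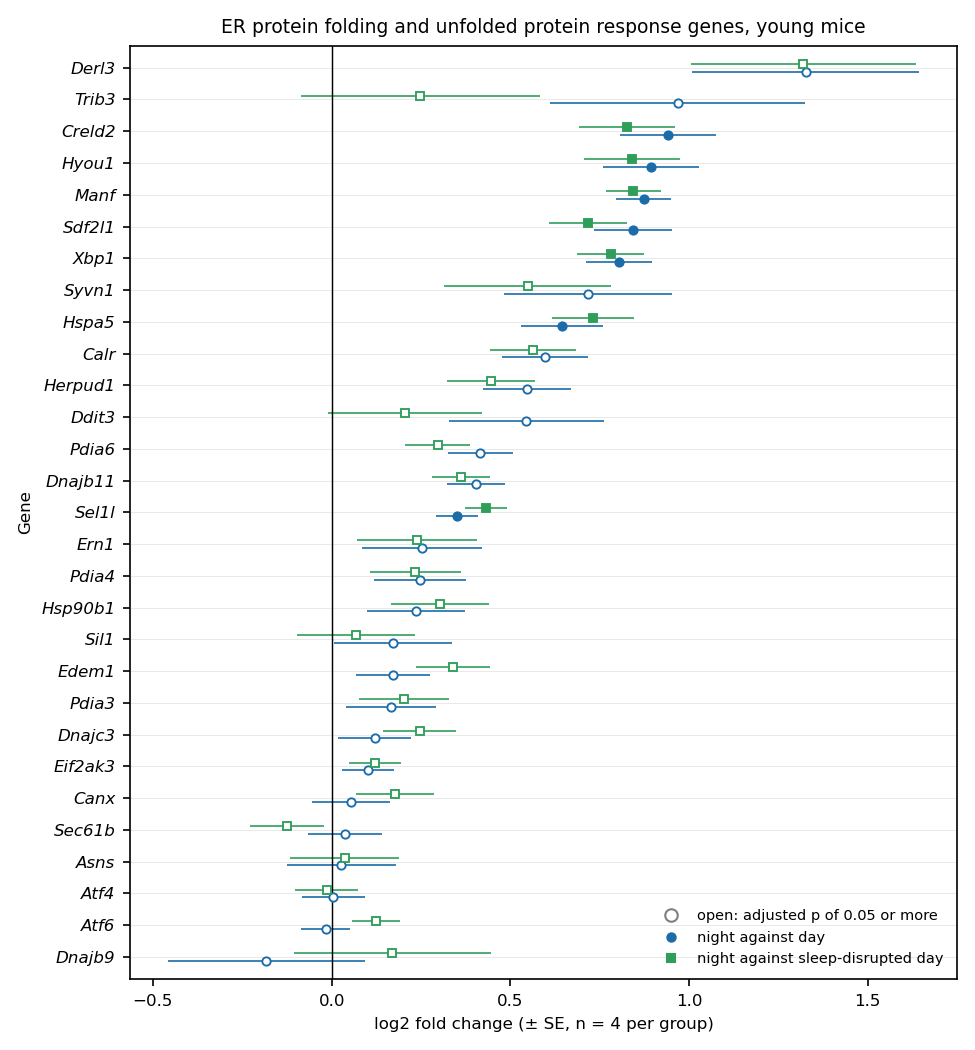
Log2 fold change of each ER folding and unfolded protein response gene in young mice (x axis, bars are ± SE, n = 4 mice per group) at night against day and against sleep-disrupted day, with filled symbols for an adjusted p under 0.05. Manf lies at 0.87 and 0.84, and 27 of the 29 genes are above 0 in each comparison.

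Other named genes that were higher at night were Lonrf3 (1.40 ± 0.26), Lbh (1.06 ± 0.14) and the linker histone gene H1f4 (0.92 ± 0.15). Named genes that were lower were Rsad1 (-0.94 ± 0.12), the cadherin gene Cdh18 (-0.70 ± 0.13) and Hmgb3 (-0.64 ± 0.09). The interleukin 1 receptor gene Il1r1 (0.60 ± 0.11, adjusted p = 0.0443), in the list of inflammatory cytokines and NF-kB, rose too. Of 32 lists tested, 9 were higher and 4 lower at night. Higher were, with ER folding, the inflammatory list (median 0.29, adjusted p = 5.69e-04), macrophage markers (0.62, 6.11e-04), cytosolic ribosome (0.25, 4.37e-06), complement (0.41, 0.0322), heat shock, immediate early genes and mural markers (each 0.0151), and fibroblast markers (0.0102). Lower were motile cilia (-0.05, 0.0108), ependyma markers (-0.23, 0.0322), choroid epithelium markers (-0.07, 0.0345) and lipid oxidation (-0.10, 0.0476). Each of these 12 lists had an adjusted p of 0.712 with an estimated correlation. The macrophage score was 2.35 log2 CPM at night and 1.78 at day (n = 4 and 4). Its exact permutation p was 0.257 (adjusted p = 0.735). Night library 4 had a score of 3.405, against 1.79 to 2.19 in the other night and 1.20 to 2.095 in the day libraries. Scores of fibroblast, mural, ependyma and choroid epithelium markers had an exact permutation p of 0.229 to 0.371 (adjusted p = 0.685 to 0.841). The lists of CSF ion and water transport (adjusted p = 0.338), secreted CSF proteins (0.166), carriers (0.362) and junctions (0.866) did not pass, and of their members 1 carrier was higher and 1 lower adjusted over the list alone: Slc22a8, an organic anion transporter (0.71 ± 0.17), and Slco1a4 (-0.53 ± 0.13).

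The count of 40 became 258 with DESeq2, 2829 with limma-voom, 13 with only the compared groups, 63 with the neural and 17 with the stromal covariate, 199 with the GC correction and 1143 with surrogate variables. It was 109 without young night library 4, 15 without day library 3, 18 without day library 4, 20 without night library 1, 21 without day library 1, and 22 without night library 2 or night library 3. Of the genes named by fold change or as clock members, Arntl, Nfil3, Cry1, Manf, Nr1d1, Nr1d2, Bhlhe41 and Rsad1 stayed called in every alternative. Calls were lost in 11 of 19 alternatives for Lonrf3, 8 for Hyou1, 7 for Per3, 6 each for Creld2 and Npas2, 2 for Hmgb3 and 1 for Lbh. Of 18 alternatives, calls were lost in 10 for Cdh18 and in 8 each for Ciart and H1f4.

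Sleep disruption was compared with undisturbed day at the same ZT to separate time of day from sleep. Clock genes in sleep-disrupted mice stayed near their day values: Nr1d1 differed by 0.17 ± 0.21 on the log2 scale, Arntl by 0.19 ± 0.17, Cry1 by -0.06 ± 0.09, Per1 by 0.12 ± 0.29, Per2 by 0.05 ± 0.18 and Dbp by 0.23 ± 0.37 (SE, n = 4 per group, adjusted p = 0.861 or higher). The metallothionein genes Mt1 (0.62 ± 0.19) and Mt2 (0.94 ± 0.28), which bind metals and respond to stress hormones, had high values without passing (adjusted p = 0.861). No gene passed with edgeR, with DESeq2 or with limma-voom, and 359 of 14983 had an unadjusted p under 0.05. The 3 genes with the smallest p were Pvr (-0.32 ± 0.08), the ribosomal protein gene Rps29 (0.72 ± 0.19) and Srcin1 (0.37 ± 0.10), with an adjusted p of 0.861 each.

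Gene lists shifted slightly after sleep disruption without any member of the 5 lists that passed being called, even adjusted over the list alone. Of 32 lists, 4 were higher and 1 lower. Cytosolic ribosome genes (51 of 52 positive, median 0.25, adjusted p = 1.90e-13) and nuclear genes of respiration (median 0.17, 1.18e-06) were higher, as were cholesterol synthesis and oxidative stress (0.0456 each). Interferon response genes were lower (median -0.31, 28 of 33 not positive, adjusted p = 6.44e-07), with Oasl2, a gene induced by interferon, at -0.73 ± 0.20. With an estimated correlation the adjusted p was 0.970 for interferon response and 0.997 for the other 4. The score of lymphocyte and neutrophil markers was lower after sleep disruption (-0.99, against -0.10 at day, exact permutation p = 0.0286, n = 4 and 4, adjusted p = 0.343), and 1 of the 4 members tested was lower adjusted over the list alone. Core clock (fry for change either way, 0.814), ER folding (0.989), glucocorticoid response (0.493) and immediate early genes (0.926) did not pass. In simulated data of this size, with genes drawn independently, 40.3% of genes changed 1.5-fold and 68.2% of genes changed 2-fold were called.

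Young night was also compared with sleep-disrupted day, where the mice had been kept from normal sleep at day. The same clock and ER genes stood out. Arntl was higher at night by 2.32 ± 0.17 (n = 4 per group, adjusted p = 4.83e-05), Nfil3 by 1.49 ± 0.16, Cry1 by 1.22 ± 0.09 and Npas2 by 0.67 ± 0.12. Lower at night were Nr1d1 (-3.19 ± 0.24), Ciart (-1.93 ± 0.35), Nr1d2 (-1.44 ± 0.16), Bhlhe41 (-1.23 ± 0.15) and Per3 (-0.98 ± 0.14). Of 14983 genes, 57 were called, 28 higher and 29 lower. With those called at night against day, 18 higher and 14 lower genes were shared, where independent lists would share 0.0392 and 0.0368 and the night libraries are common to both comparisons. Of 24 core clock genes 5 rose, 5 fell and 14 did not pass (6 and 7 adjusted over the list alone). Other named genes were Lbh (1.12 ± 0.14), H1f4 (1.08 ± 0.15) and the guanine nucleotide exchange factor gene Rapgef5 (1.27 ± 0.22) above, and the cold-inducible RNA-binding protein gene Cirbp (-1.02 ± 0.19), Rsad1 (-0.81 ± 0.12) and Arhgef33 (-0.77 ± 0.13) below.

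The ER folding list was higher again (27 of 29 positive, median 0.30, camera adjusted p = 2.63e-18, 0.00390 with an estimated correlation, fry 3.58e-05). Of its members 7 rose and 22 did not pass, and 13 rose adjusted over the list alone. Manf (0.84 ± 0.08), Hyou1 (0.84 ± 0.13), Creld2 (0.83 ± 0.13) and Xbp1 (0.78 ± 0.09) were among them. Of 32 lists 12 were higher and 4 lower at night. Macrophage markers were higher (median 1.00, adjusted p = 2.70e-07), none of 20 past over all genes and 7 adjusted over the list alone, with the complement gene C1qb at 1.39 ± 0.40. The inflammatory list (median 0.44, 4.21e-07), complement (0.51, 1.27e-04), interferon response (0.11, 0.00245), antigen presentation (0.0361), immediate early genes (0.00355), heat shock (0.00467) and amyloid-beta handling (0.0471) were higher too. So were markers of fibroblasts (0.47, 3.17e-04), endothelium (0.00467) and mural cells (0.00391). Lower were lipid oxidation (median -0.16, 1.27e-04, 1 of 24 called and 6 adjusted over the list alone), respiration (8.42e-05), motile cilia (4.84e-05) and ependyma (0.0474). With an estimated correlation the adjusted p of all lists here but ER folding lay between 0.445 and 0.659. The macrophage score itself was 2.35 log2 CPM at night and 1.61 after sleep disruption, and the stromal score 2.94 and 2.52 (exact permutation p = 0.0286 each, n = 4 and 4, adjusted p = 0.343).

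The count of 57 became 303 with DESeq2, 1103 with limma-voom, 16 with only the compared groups, 89 with the neural and 24 with the stromal covariate, 333 with the GC correction and 933 with surrogate variables. It was 86 without night library 4, 22 without sleep-disrupted library 2, 24 without sleep-disrupted library 3, 34 without sleep-disrupted library 4, and 27, 31 and 29 without night libraries 1, 2 and 3. Of the genes named by fold change or as clock members, Arntl, Nfil3, Cry1, Lbh, Manf, Nr1d1, Nr1d2 and Bhlhe41 stayed called in every alternative. Calls were lost in 8 of 19 alternatives each for Hyou1, Creld2, Cirbp and Npas2, 7 for Rapgef5, 5 for Rsad1 and 1 for Per3. Of 18 alternatives, calls were lost in 10 for Arhgef33, 8 for Ciart and 1 for H1f4.

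Across 14983 genes, the difference of sleep disruption from day and that of night from day had a Pearson r of 0.415. Both use the same day libraries. In simulations of unchanged groups against shared day libraries the mean r was 0.510, and 69 of 100 draws were as high. With 2 day libraries used for each comparison, r over the 6 ways to split them had a mean of 0.0132 and ran from -0.222 to 0.194. Genes are not independent replicates, so no p is given. No likeness between both changes was detectable beyond the shared libraries.

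Aged wild-type night was compared with day to see whether the time of day also marks the aged tissue. Tsc22d3 (Gilz), a glucocorticoid-induced gene, rose at night by 1.33 ± 0.13 (SE, n = 4 per group, Entrez 14605, chromosome X, 140539528 to 140600522, adjusted p = 3.14e-04). Clock genes that did not pass over all genes included Nr1d1 at -1.51 ± 0.23 (adjusted p = 0.0583), Dbp at -1.65 ± 0.27 (0.0756), Nfil3 at 1.5 ± 0.26 (0.0888), Arntl at 1.20 ± 0.37, Cry1 at 0.99 ± 0.21, Per2 at 1.43 ± 0.44 and Per1 at 1.15 ± 0.31 (0.144 each). Of 24 core clock genes 1 rose, none fell and 23 did not pass, and adjusted over the list alone 8 rose and 4 fell (fry for change either way, adjusted p = 7.32e-09). Of 16065 genes tested 2 were called, both higher at night, with 5002 at an unadjusted p under 0.05.

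Glucocorticoid response genes were higher at night as a list (27 tested, median 0.33, adjusted p = 0.0194, fry 0.0122), with 1 past over all genes and 8 higher and 1 lower adjusted over the list alone. The sulfotransferase gene Sult1a1 was at 0.85 ± 0.17 and the hypoxia-inducible factor gene Hif3a at 2.55 ± 0.74. Of immediate early genes (27 tested, median 0.85, adjusted p = 1.23e-04) none passed over all genes and 11 were higher adjusted over the list alone, with Fos at 2.203 ± 0.594 and Egr1 at 2.184 ± 0.587. Lists of choroid plexus function had lower values at night: CSF ion and water transport (median -0.43, adjusted p = 3.83e-04), carriers (-0.46, 6.20e-04), secreted CSF proteins (-0.33, 0.00619), junctions (-0.40, 0.0128) and amyloid-beta handling (-0.42, 0.00330). None of their members passed over all genes, and 8 of 35 ion and water transport genes were lower adjusted over the list alone, among them the water channel Aqp1 (-1.58 ± 0.47) and the cotransporter Slc12a2 (Nkcc1, -1.33 ± 0.41). This count shows no excess over other genes, as 5002 of all 16065 had an unadjusted p under 0.05. Lipid oxidation (-0.51, 6.00e-05), cholesterol synthesis (-0.33, 0.00515) and autophagy (-0.22, 0.0219) were lower as lists and cytosolic ribosome higher (0.34, 2.78e-05, 22 of 52 adjusted over the list alone). With an estimated correlation the adjusted p of these lists was 0.545 to 0.661. ER folding did not pass in these mice (median -0.25, adjusted p = 0.429), and its median was -0.007 with the neural covariate. The neural score was higher in night than in day libraries (5.50 against 2.78 log2 CPM). A different tissue mix thus stays open as a cause of the lower lists of choroid plexus function.

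Neural markers moved with these lists. Neuron markers were higher at night by a median of 3.17 (adjusted p = 2.67e-06, 18 of 20 adjusted over the list alone, with the synaptic gene Syt1 at 2.53 ± 0.71), oligodendrocyte markers by 1.83 (3.15e-04), astrocyte markers by 1.97 (1.67e-04, 2 of 15) and ependyma markers by 0.70 (0.0389). Choroid epithelium markers were lower by a median of -0.69 (adjusted p = 4.22e-05, 9 of 19 adjusted over the list alone, with Cldn2 at -1.22 ± 0.38). All 5 had an adjusted p of 0.545 with an estimated correlation. Erythroid markers did not pass (8 tested, median 1.54, adjusted p = 0.220). The erythroid score was 1.96 at night and 0.876 at day, the ependyma score 4.76 and 3.72, the choroid epithelium score 9.30 and 9.97, and the GC trend 0.391 and -0.132 (exact permutation p = 0.0286 each, n = 4 and 4, adjusted p = 0.343).

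The count of 2 was 1290 with DESeq2, 8299 with limma-voom, 5 with the neural covariate, 6 with the GC correction, 9 with surrogate variables, 3 with upper-quartile scaling, 4033 with only the compared groups, and 7155 without J20+ day library 1 and J20+ night library 2. It was 100 without aged wild-type night library 3, whose neural score is the lowest of its group at 3.77, and 3 without night library 1. Upper-quartile scaling set the median of all genes at 0.15, against 0.03.

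Aged J20+ night was compared with J20+ day in the same way. Clock genes led again: Nfil3 rose by 1.67 ± 0.26 and Cry1 by 1.34 ± 0.22 (n = 4 per group, adjusted p = 0.0451 each), while Nr1d1 fell by 2.13 ± 0.24 (0.00194) and Dbp, an output transcription factor of the clock, by 1.69 ± 0.27 (0.0451). Tsc22d3 rose by 0.78 ± 0.13 and the splicing regulator gene Tra2a by 1.49 ± 0.23 (0.0451 each). Of 20 alternatives, the call was lost in 16 for Tsc22d3, 15 for Tra2a, 15 for Dbp, 14 for Nfil3, 11 for Cry1 and 1 for Nr1d1, and it was lost without any 1 of the 8 libraries for Tsc22d3 and Tra2a. Of 16065 genes tested 7 were called, 5 higher and 2 lower. Of 24 core clock genes 3 rose, 2 fell and 19 did not pass (5 and 4 adjusted over the list alone, fry for change either way, adjusted p = 8.25e-11). Arntl was at 1.501 ± 0.374 (0.438) and Per2 at 1.61 ± 0.45 (0.521).

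ER folding genes were higher at night in J20+ mice as a list (24 of 30 positive, median 0.15, adjusted p = 3.58e-04), none past over all genes and 4 adjusted over the list alone: Xbp1 (0.97 ± 0.19), Creld2 (1.11 ± 0.23), Manf (0.98 ± 0.23) and Syvn1, an ER ubiquitin ligase gene (0.88 ± 0.24). Without J20+ night library 4 the list did not pass (adjusted p = 0.100). Heat shock (0.25, 3.58e-04), glucocorticoid response (0.09, 0.0359), respiration (0.19, 3.22e-04), mitochondrial genome (0.50, 3.93e-04) and cytosolic ribosome (0.17, 3.22e-04) were higher too. Interferon response (median -0.54, 3.22e-04), complement (-0.33, 0.00879), lipid oxidation (-0.12, 0.0237) and markers of macrophages (-0.34, 3.22e-04), fibroblasts (-0.56, 0.00220), mural cells (0.00660), ependyma (0.00749), astrocytes (-1.46, 0.0237), neurons (-0.70, 0.0283) and endothelium (0.0490) were lower. With an estimated correlation the adjusted p of these 16 lists was 0.687 to 0.913. CSF ion and water transport did not pass (-0.01, 0.748), and neither did choroid epithelium markers (0.01, 0.904). Without J20+ day library 1, which has the highest neural score of its group (5.36), neuron and astrocyte markers turned higher (adjusted p = 0.711 and 0.746).

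The count of 7 became 76 with DESeq2, 274 with limma-voom, 41 with surrogate variables, 4 with no filter, 3 with upper-quartile scaling, with the filter of 10 CPM or with the GC correction, 2 with RLE scaling (1 higher and 1 lower) or with the stromal covariate, and 1 with only the compared groups. It was 2 without any 1 of J20+ day libraries 1, 2, 3 or 4 or of night libraries 3 and 4, and 4 without night library 1.

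The night-day changes of the 3 sets of mice, which share no libraries, were set side by side. Across the 24 core clock genes the log2 changes of young mice had a Pearson r of 0.694 with those of aged wild-type mice and 0.855 with those of J20+ mice, and the aged sets had an r of 0.569 with each other. Of the 40 genes called in young mice, 33 had the same sign in aged wild-type and 39 in J20+ mice. Over all genes the r was 0.167, 0.163 and -0.253, and Spearman's rho 0.265, 0.255 and 0.147. Among genes of at least 3 log2 CPM the aged pair had an r of 0.0130 and a rho of 0.445. The aged pair had an r of -0.7001 without J20+ night library 2 and 0.642 without J20+ day library 1, and the young and aged wild-type pair -0.0534 without young night library 4. The young and J20+ pair had an r of 0.0433 without young day library 1 and 0.428 without young night library 4. Genes are not independent replicates.

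J20+ mice were compared with wild-type littermates to see what amyloid status changes in the aged tissue. Over both times no gene passed with edgeR among 16065 (n = 8 and 8), with 3209 at an unadjusted p under 0.05, 315 with DESeq2 and 11447 with limma-voom. The smallest p were those of the calcium-binding protein gene Necab2 (-0.70 ± 0.12), 2600006K01Rik (-1.59 ± 0.31) and the aldehyde oxidase gene Aox3 (0.93 ± 0.19), with an adjusted p of 0.233 each. Cytosolic ribosome genes were lower in J20+ mice as a list (median -0.27, adjusted p = 1.45e-10, none past over all genes, 22 of 52 adjusted over the list alone), as were nuclear (-0.23, 1.72e-06) and mitochondrial genes of respiration (-0.46, 1.12e-04). Junction genes (0.31, 0.00767), cholesterol synthesis (0.27, 0.00406), CSF ion and water transport (0.16, 0.0358) and fibroblast markers (0.40, 0.0164) were higher. The bicarbonate transporter gene Slc4a5 was at 0.50 ± 0.18 and the collagen gene Col1a2 at 0.75 ± 0.17. Markers of neurons (-0.83, 1.59e-04), oligodendrocytes (-1.80, 1.12e-04), astrocytes (-0.50, 0.00795) and lymphocytes and neutrophils (-0.52, 0.00689) were lower. All 11 had an adjusted p of 0.686 with an estimated correlation. As neural markers were lower too, a different tissue mix stays open as a cause of the other shifts. The lists of amyloid-beta handling (0.0733) and secreted CSF proteins (0.770) did not pass, and neither did the core clock by fry for change either way (0.262). The count of 0 was 6913 without J20+ night library 2, 572 without aged wild-type day library 4, 9118 without J20+ day library 1 and night library 2, and 1 with surrogate variables.

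At day no gene passed with edgeR (n = 4 and 4), with 300 at an unadjusted p under 0.05, 0 with DESeq2 and 2363 with limma-voom. The cartilage proteoglycan gene Epyc (3.12 ± 0.73), Tbc1d1 (2.25 ± 0.59) and the lipid droplet gene Cidea (1.93 ± 0.53) had the smallest p, with an adjusted p of 0.989 each. Markers of fibroblasts (median 0.61, adjusted p = 5.68e-06), macrophages (0.32, 1.83e-06), complement (0.30, 0.00185), mural cells (0.29, 0.0158), endothelium (0.31, 0.0239) and astrocytes (1.20, 0.0486) were higher in J20+ mice as lists. Nuclear (-0.20, 4.85e-13) and mitochondrial (-0.53, 3.18e-08) genes of respiration, cytosolic ribosome (-0.19, 1.06e-10), ER folding (-0.14, 0.0287), secreted CSF proteins (-0.07, 0.0256), choroid epithelium markers (-0.06, 0.0105) and lymphocyte and neutrophil markers (-0.59, 0.0140) were lower. No member passed, even adjusted over the list alone, and the adjusted p of the 13 lists was 0.535 to 0.848 with an estimated correlation. J20+ day library 1 had the highest stromal score of its group, 4.41 against 3.11 to 3.24.

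At night 1 gene of 16065 passed, with 5129 at an unadjusted p under 0.05. Necab2 fell by 1.31 ± 0.17 in J20+ mice (n = 4 per group, Entrez 117148, chromosome 8, 119446719 to 119472640, adjusted p = 0.0355), from 31.7 ± 6.54 CPM (SD) in wild-type to 12.8 ± 2.70 in J20+ libraries. Lists of choroid plexus function were higher: CSF ion and water transport (median 0.36, adjusted p = 0.00373, 7 of 35 adjusted over the list alone), carriers (0.39, 0.0106), junctions (0.45, 0.00948, 9 higher and 2 lower), amyloid-beta handling (0.41, 0.0291, 10 of 34), cholesterol synthesis (0.53, 2.49e-04, 8 of 26), lipid oxidation (0.29, 0.0259) and ER folding (0.34, 0.0325, 6 higher and 1 lower). The bicarbonate transporter gene Slc4a10 was at 1.74 ± 0.48 and Ace, which cleaves amyloid-beta, at 1.56 ± 0.44. The counts adjusted over a list alone show no excess over other genes, as 5129 of all 16065 had an unadjusted p under 0.05. The neural score was 2.57 log2 CPM in J20+ and 5.50 in wild-type night libraries. A different tissue mix thus stays open as a cause of the higher lists of choroid plexus function. Immediate early genes (-0.50, 0.00255), cytosolic ribosome (-0.37, 5.83e-07), nuclear (-0.27, 0.00610) and mitochondrial (-0.37, 0.0180) genes of respiration, cell cycle (-0.51, 0.0130) and lymphocyte and neutrophil markers (-0.71, 0.0259) were lower. Neural markers moved with these lists: neuron markers were lower by a median of -2.81 (1.86e-07), oligodendrocyte markers by -2.94 (1.74e-05), astrocyte markers by -2.46 (4.36e-05) and ependyma markers by -0.54 (0.00407), and choroid epithelium markers were higher by 0.66 (0.00373). The adjusted p of the 18 lists was 0.644 to 0.701 with an estimated correlation. With the neural score as a covariate, the marker lists of neurons, oligodendrocytes and astrocytes turned higher without passing (adjusted p = 0.946, 0.946 and 0.888). The covariate is built from the genes of these lists, so this loss was set in advance and tells nothing about its cause.

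The call of Necab2 at night was lost with RLE and upper-quartile scaling, with no filter, with the filter of 10 CPM, with the neural covariate, the GC correction or surrogate variables, and with only the compared groups. DESeq2 called 3044 genes, limma-voom 11589, the stromal covariate 3, and the fit without J20+ day library 1 and night library 2 called 10135. The count was 9414 without J20+ night library 2, 107 without aged wild-type night library 3, and 0 without any other 1 of the 8 night libraries. Upper-quartile scaling set the median of all genes at -0.16, against -0.01.

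App, the mouse gene of the amyloid precursor protein, and Zbtb20, near or in which the J20 transgene is reported to lie, were not called in any genotype comparison. App differed by 0.24 ± 0.24 over both times (adjusted p = 0.544), by -0.10 ± 0.34 at day (0.989) and by 0.57 ± 0.34 at night (0.255), and Zbtb20 by 1.11 ± 0.61 (0.297), 0.17 ± 0.85 (0.989) and 2.05 ± 0.89 (0.136). In J20+ day libraries 1 to 4 App was at 1919, 2192, 1380 and 1436 CPM and Zbtb20 at 9.60, 3.27, 16.2 and 17.97 CPM. In J20+ night libraries App was at 1906, 564, 1852 and 1532 CPM and Zbtb20 at 5.73, 3.48, 17.8 and 14.3 CPM. In aged wild-type day libraries App was at 1945, 1955, 1842 and 1535 CPM and Zbtb20 at 3.37, 2.05, 2.42 and 31.1 CPM. In aged wild-type night libraries App was at 1575, 1030, 1276 and 882.0 CPM and Zbtb20 at 3.35, 3.28, 2.28 and 3.43 CPM. J20 status was not checked here, as the counts are of mouse genes. Chosen after their values were seen, the Y-linked gene Ddx3y was at 78.4 and the transthyretin gene Ttr at 11520 CPM in J20+ night library 2, against 250.4 to 273.0 and 6130 to 7219 in the other J20+ night and 80.8 to 130 and 10530 to 11460 in aged wild-type night libraries. In aged wild-type day library 4 they were at 309 and 7780 CPM, against 171 to 199 and 10050 to 11060 in the other aged wild-type day and 200.5 to 325 and 4728 to 8942 in J20+ day libraries. Whether a wrong label or the tissue mix accounts for these 2 libraries was not tested, so the genotype counts hold only for the labels as given.

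Whether the night-day change differs between genotypes was tested by the interaction of genotype and time. No gene passed with edgeR, with 1992 at an unadjusted p under 0.05, 3 with DESeq2 and 5351 with limma-voom. Of the core clock list, fry's test for change either way did not pass (adjusted p = 0.579), and Nr1d1 differed by -0.62 ± 0.32 (adjusted p = 0.431). The smallest p were those of 1500009C09Rik (-1.62 ± 0.29), the glycogen phosphatase subunit gene Ppp1r3d (-3.28 ± 0.62) and Necab2 (-1.21 ± 0.24), with an adjusted p of 0.359 each. Of 34 lists 9 had a higher and 9 a lower night-day change in J20+ than in wild-type mice. Higher were choroid epithelium markers (median 0.69, adjusted p = 1.14e-05), cholesterol synthesis (0.53, 1.11e-04), CSF ion and water transport (0.46, 6.22e-04), ER folding (0.55, 8.63e-04), carriers (0.00519), lipid oxidation (0.00563), secreted CSF proteins (0.00841), autophagy (0.00847) and amyloid-beta handling (0.0241). Lower were markers of neurons (-3.66, 1.48e-10), astrocytes (-3.92, 2.30e-07, 14 of 15 adjusted over the list alone), oligodendrocytes (-2.02, 4.06e-05), macrophages (-0.74, 5.74e-05) and ependyma (1.13e-04), immediate early genes (-0.74, 9.30e-05), cell cycle (0.00452), interferon response (0.00841) and cytosolic ribosome (0.0186). These lists had an adjusted p of 0.584 to 0.734 with an estimated correlation. As neural and epithelial markers shifted too, a different tissue mix stays open as a cause of the other shifts. In simulated data of this size, with genes drawn independently, 50.0% of genes changed 4-fold were called and none changed 2-fold. The count of 0 was 3409 without J20+ night library 2, and upper-quartile scaling set the median of all genes at -0.06, against 0.06.

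Whether the night-day change differs between young and aged wild-type mice was tested by the interaction of age and time. No gene passed with edgeR among 16590, with 2877 at an unadjusted p under 0.05, 5 with DESeq2 and 5916 with limma-voom. Within the core clock list, Nr1d1 had a smaller drop at night in aged mice, a difference of 1.48 ± 0.35 (adjusted p = 0.265 over all genes and 0.00612 adjusted over the list alone), and Arntl differed by -1.32 ± 0.44 (0.0686 over the list alone). The list did not pass fry's test for change either way (0.114). The smallest p over all genes were those of Sfmbt2 (-1.25 ± 0.27), the enolase gene Eno1b (-2.13 ± 0.47) and the integrin gene Itgal (-4.89 ± 1.12), with an adjusted p of 0.265 each. Itgal was at 21.8 CPM in young night library 4 and at 0.554 to 0.835 CPM in the other young night libraries. ER folding genes had a lower night-day change in aged mice (median -0.65, adjusted p = 1.65e-05, 10 of 30 lower and 1 higher adjusted over the list alone, but 0.406 with an estimated correlation), with Hyou1 at -1.12 ± 0.31. In aged wild-type mice alone the list's night-day median was -0.25, and -0.007 with the neural covariate. In J20+ mice of the same age and batch it was 0.15 (camera adjusted p = 3.58e-04). A different tissue mix thus stays open as a cause of the difference between ages. Of 34 lists 7 were higher and 12 lower. Higher were markers of neurons (2.88, 6.65e-08), oligodendrocytes (1.94, 3.02e-06), astrocytes (1.81, 5.87e-05) and ependyma (0.70, 0.00188), immediate early genes (0.0355), cell cycle (0.00229) and mitochondrial genome (0.0135). Lower were, with ER folding, choroid epithelium markers (-0.71, 1.50e-04, 10 of 19), secreted CSF proteins (-0.67, 1.50e-04), CSF ion and water transport (-0.47, 9.19e-04), carriers (0.00160), junctions (0.00498), amyloid-beta handling (9.16e-04), cholesterol synthesis (3.96e-04), lipid oxidation (0.00188), autophagy (0.00160), complement (0.0379) and the inflammatory list (0.00261, 3 of 26). The adjusted p of these lists was 0.406 to 0.671 with an estimated correlation. The count of 0 was 2 without aged wild-type night library 3 and 854 with only the compared groups, and upper-quartile scaling set the median of all genes at 0.07, against -0.06. Age and batch cannot be told apart here, as each batch holds mice of 1 age.

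Aged wild-type libraries were compared with young libraries over both times, which is also batch 2 against batch 1. Of 16590 genes, 13330 differed, 7092 higher and 6238 lower in aged libraries (n = 8 and 8). Among the highest fold changes were those of Dpm3, of mannose donor synthesis (6.16 ± 0.29), the respiratory chain gene Ndufa6 (5.87 ± 0.24), Aatk (5.81 ± 0.82), the myelin genes Mag (5.77 ± 1.05) and Mobp (5.37 ± 1.12), the tight junction gene Cldn3 (5.54 ± 0.34), the ribosomal protein gene Rpl36 (5.50 ± 0.28), Lmtk3 (5.36 ± 0.54) and Josd2 (5.34 ± 0.33). The lowest were those of Tent5d (-4.19 ± 0.44), the prostaglandin synthase gene Ptgs2 (Cox-2, -4.12 ± 0.44), the amyloid-beta degrading peptidase gene Mme (neprilysin, -3.95 ± 0.28), Lmbrd2 (-3.91 ± 0.56), Uhmk1 (-3.65 ± 0.54), Hgf (-3.48 ± 0.36), Deptor (-3.48 ± 0.51), C1galt1 (-3.45 ± 0.34), Mob1b (-3.39 ± 0.40) and Mob1a (-3.38 ± 0.36). Log2 fold change rose with the GC content of the transcript (Spearman's rho of 0.789 across 15193 genes, not independent replicates), from a median of -1.48 in the tenth of genes with the lowest GC content to 2.77 in the tenth with the highest.

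Of 34 lists 3 were higher in aged libraries and none lower. Cytosolic ribosome genes were higher (43 higher and 6 lower of 52, median 1.70, adjusted p = 2.55e-07), as were nuclear genes of respiration (31 higher and 10 lower of 50, 0.78, 0.0109) and antigen presentation (19 higher and 1 lower of 20, 1.97, 2.75e-04). Tap2 (3.08 ± 0.14) and Tap1 (1.96 ± 0.14), the peptide transporter of antigen presentation, were among them. All 3 had an adjusted p of 0.991 with an estimated correlation, and with the GC correction antigen presentation turned lower without passing (adjusted p = 0.560). The other 31 lists, among them the core clock with 11 higher and 8 lower, CSF ion and water transport with 15 and 16 and choroid epithelium markers with 3 and 12, had an adjusted p of 0.203 or more. No batch holds mice of both ages, so age and batch cannot be told apart.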

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

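Of the tests weighed in this part, those of brain tissue in the dissection and of an even rise of all other cell types were chosen after the result was seen, and that of GC content after the data were seen.

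Values far from the other 3 libraries of their group were found by Dixon's test (95% critical value) in 8 of 105 groups of library measures and 23 of 262 groups of gene values, of which 18 are given here. Chance alone sets apart about 1 in 20 groups. J20+ night library 2 stood apart in its GC trend (0.838, others -0.370 to -0.318), choroid epithelium markers (9.06, others 10.1) and ependyma markers (4.30, others 3.16 to 3.33). J20+ day library 1 stood apart in the stromal score (4.41, others 3.11 to 3.24) and fibroblast markers (4.83, others 3.45 to 3.62), and J20+ day library 3 in depth (43.9M, others 19.6 to 23.2). Sleep-disrupted library 1 had a stromal score of 1.99 (others 2.65 to 2.77) and sleep-disrupted library 2 ependyma markers of 2.32 (others 2.99 to 3.05).

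Among young libraries, in log2 CPM, sleep-disrupted library 1 had Dbp at 2.96 (others 4.20 to 4.27) and Tef at 7.17 (7.53 to 7.59). Night library 4 had Cry2 at 4.17 (4.86 to 4.92), Dbp at 0.58 (2.27 to 2.50), Hyou1 at 6.51 (6.97 to 6.98) and Itgal at 4.32 (-0.82 to -0.33). Night library 1 had Manf at 7.60 (7.43 to 7.45) and night library 3 Per3 at 4.72 (4.16 to 4.23). Among aged libraries, J20+ day library 3 had Tsc22d3 at 4.49 (4.82 to 4.88). J20+ night library 2 had Aox3 at 3.51 (3.89 to 3.95), App at 8.95 (10.76 to 11.05) and Csnk1e at 5.16 (4.31 to 4.45). Aged wild-type day libraries 3 and 1 had Aox3 at 2.83 (3.38 to 3.47) and Npas2 at 4.12 (4.45 to 4.48). Aged wild-type night library 4 had 1500009C09Rik at 5.28 (4.78 to 4.85) and Fbxl21 at 0.73 (1.35 to 1.45), and night library 3 had Cry2 at 5.53 (5.95 to 6.03) and Csnk1e at 4.73 (5.14 to 5.18).

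Lists passed the interaction tests of night-day change by camera with the preset correlation, while no gene was called. Between genotypes, 9 lists had a higher and 9 a lower night-day change in J20+ mice, neural and epithelial markers among them. With an estimated correlation none of these passed (adjusted p = 0.584 to 0.734), and 12 of 100 splits gave as many. Between ages, 7 lists had a higher and 12 a lower night-day change in aged mice. None of these passed with an estimated correlation (adjusted p = 0.406 to 0.671), and 16 of 100 splits gave as many. Nr1d1 had an adjusted p of 0.00612 over the core clock list alone and 0.265 over all genes. Each batch holds mice of 1 age, so age and batch cannot be told apart.

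In aged wild-type mice, neural markers were higher and choroid epithelium markers lower in night than in day libraries by camera with the preset correlation. None of these lists passed with an estimated correlation (adjusted p = 0.545), and the neural score differed with an exact permutation p of 0.0571 (adjusted p = 0.343). The median of neural markers was 2.33 after the GC correction, which argues against the GC trend as the whole cause. Stromal markers had a median of -0.0750 (SD over genes 0.60) beside 2.32 (SD 0.96) for neural markers, which argues against a lower share of epithelium with all other types raised alike. Brain tissue in the dissection stays open: within groups of the 16 aged libraries the neural and epithelial scores had an r of -0.813 (rho -0.808, permutation p = 8.5e-04, -0.750 without the 2 farthest libraries), while with the neural covariate the epithelial markers kept a median of -0.16 (-0.69 without it) and an adjusted p of 0.0119 with the preset correlation. The transthyretin gene Ttr did not fall with these markers: it was at -0.03 ± 0.20 (log2, SE) without the neural covariate and at -0.16 ± 0.23 with it. A change of the tissue itself with time of day also stays open, as untested.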

How the results depend on the processing

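The GC correction, surrogate variables and the fit without J20+ day library 1 and J20+ night library 2 were chosen after seeing the data. The causes of the changes below were not tested. No paired analysis was possible because replicate numbers follow the order of the sample records and pair no animals.

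Sleep disruption against day gave 0 genes in every setting, and aged against young 9745 to 14352. Of the called genes that the naming rule picks, 10 of 21 at young night against day, 10 of 21 at night against sleep disruption, 2 of 2 in aged wild-type and 1 of 7 in J20+ mice were called in every setting, and Necab2 at night was not.

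Counts of genes moved by more than 1.5 times as follows. Young night against day (40): DESeq2 258, limma-voom 2829, neural covariate 63, stromal covariate 17, GC correction 199, surrogate variables 1143, compared groups alone 13, and 15 to 109 with 1 library left out. Night against sleep disruption (57): 303, 1103, 89, 24, 333, 933 and 16 in the same order, and 22 to 86. Aged wild-type night against day (2): DESeq2 1290, limma-voom 8299, neural covariate 5, GC correction 6, surrogate variables 9, compared groups alone 4033, without the 2 J20+ libraries 7155, and 2 to 100 with 1 library left out. J20+ night against day (7): RLE 2, upper quartile 3, DESeq2 76, limma-voom 274, no filter 4, filter of 10 CPM 3, stromal covariate 2, GC correction 3, surrogate variables 41, compared groups alone 1, and 2 to 5.

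J20+ against wild-type over both times (0): DESeq2 315, limma-voom 11447, surrogate variables 1, without the 2 J20+ libraries 9118, and 0 to 6913 with 1 library left out. At day (0): limma-voom 2363. At night (1): DESeq2 3044, limma-voom 11589, stromal covariate 3, without the 2 J20+ libraries 10135, and 0 to 9414. It was 0 with RLE, upper quartile, no filter, the filter of 10 CPM, the neural covariate, the GC correction, surrogate variables and the compared groups alone. Genotype by time (0): DESeq2 3, limma-voom 5351, and 0 to 3409. Age by time (0): DESeq2 5, limma-voom 5916, compared groups alone 854, and 0 to 2.

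Lists that changed direction were mural markers at young night against day with the stromal covariate (adjusted p = 0.964), oligodendrocyte (0.179) and astrocyte markers (0.540) in aged wild-type night against day with the neural covariate, and neuron (0.946), oligodendrocyte (0.946) and astrocyte markers (0.888) in J20+ against wild-type at night with the neural covariate. Each of these covariates is built in part from the genes of the list named, so these losses were set in advance. With 1 library left out, neuron markers in J20+ night against day ran from 2.75e-06 to 0.711 and astrocyte markers from 9.22e-05 to 0.746, with the direction changed at the higher value. Antigen presentation in aged against young changed direction with the GC correction (0.560). With an estimated correlation 2 of 148 list calls stayed past the threshold. Of 111 list results described here, passing or not, some lost their pass with the direction kept. These were 23 with the neural covariate, 23 with the filter of 10 CPM, 15 with the stromal covariate and 13 with the GC correction. They were 3 each with upper-quartile scaling and no filter, and 2 with RLE scaling. A pass was also lost 76 times with 1 library left out, and 12 times without the 2 J20+ libraries.

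The agreement of young with aged wild-type changes was 0.292 among genes of at least 3 log2 CPM, and -0.0534 to 0.237 with 1 library left out. That of young with J20+ changes was 0.312 and 0.0433 to 0.428, and that of the 2 aged sets 0.0130 (-0.253 over all genes) and -0.7001 to 0.642. The agreement of sleep disruption with night ran from 0.236 to 0.631 with 1 library left out, and over splits of the day libraries it was 0.00312, 0.0293, 0.194, -0.0864, 0.161 and -0.222.

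In simulated data 2-fold changes were called for 62.7% of genes at young night against day, 77.3% at night against sleep disruption, 34.3% in aged wild-type and 17.9% in J20+ night against day.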

Other observations

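The tests of GC content and neural tissue in aged against young libraries, and all counts of splits, were chosen after the result was seen.

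Aged against young differences were set against 3 explanations. With the GC correction 7425 of 13330 genes stayed called in the same direction, while the Spearman correlation with GC content went from 0.789 to 0.00767, and with the neural covariate 11735 stayed. This argues against either as the whole cause. The number of batches with both ages is 0, so batch and age cannot be told apart, since each batch holds mice of 1 age.

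The higher ER folding list at young night was set against 3 technical explanations. By camera with the preset correlation, its adjusted p was 1.49e-14 after the GC correction, 3.59e-18 with the stromal covariate and at most 2.64e-08 with 1 library left out, without night library 4. The list median was 0.35 in the main fit, 0.37, 0.36 and 0.34 to 0.39 in the same order. These values argue against GC content, stromal share and a single night library as the cause of the list's shift. Calls of single members did depend on the setting: 7 were called in the main fit, 10 after the GC correction, 3 with the stromal covariate and 3 to 11 with 1 library left out. A time-of-day change in ER folding is left as a hypothesis, found and tested on the same data.

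Other splits of the libraries into groups of the same sizes were counted, the real one included. For J20+ over both times and aged against young, genotype or age was shuffled within each time. For the interactions, time was shuffled within each genotype or age. This also breaks the night-day difference itself, so the shares of the interactions do not test the interaction alone. A share of 1 in 35 is the smallest that 4 against 4 libraries can give, and no share is corrected for the number of comparisons. For ER folding at young night, only the real split gave as small a p against day (1 of 35, 1.53e-17, next 7.87e-13) and against sleep disruption (1 of 35, 8.23e-20, next 1.68e-11). This list was picked for the test after its result was seen, as the one with the smallest p of 32, so the shares do not exclude chance in that choice. For counts of genes, only the real split gave as many in J20+ night against day (1 of 35, 7 genes, highest other 0), 1 of 11 comparisons examined, where the count fell to 2 without any 1 of J20+ day libraries 1 to 4 or of night libraries 3 and 4. Without night library 1 it was 4, and without night library 2 it was 5. In aged against young only the real split, which is also the division of the batches, gave as many (1 of 100, 13330, highest other 12346). A share of 1 in 100 is the smallest that 100 splits can give. Chance is not excluded at young night against day (2 of 35, 40, highest other 5559), night against sleep disruption (2 of 35, 57 and 86), aged wild-type night against day (2 of 35, 2 and 45) and J20+ against wild-type at night (3 of 35, 1 and 8573). The split with 5559 genes exchanges young night library 4 with day library 2, and that with 8573 exchanges J20+ night library 2 with wild-type night library 3. In the first of these splits, libraries with a GC trend of 0.298 to 0.551 stood against libraries at -0.85 to -0.18. In the second, libraries with a neural score of 1.06 to 3.77 stood against libraries at 4.535 to 6.485. Both splits thus follow a library measure, and whether it accounts for the larger counts was not tested. Sleep disruption and J20+ at day had 0 genes in all 35 splits. J20+ over both times, genotype by time and age by time had 0 genes, with highest others of 7947, 1146 and 756. With a count of 0 all 100 splits are as high by definition, so that share tests nothing.

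For counts of lists chance is excluded nowhere. As many lists came from 14 of 35 splits at young night against day (13, highest other 19), 31 after sleep disruption (5 and 15), 7 at night against sleep disruption (16 and 21), 10 in aged wild-type (16 and 20), 10 in J20+ night against day (16 and 24), 24 in J20+ against wild-type at day (13 and 21) and 4 at night (18 and 19). Of 100 splits, as many came from 70 for J20+ over both times (11 and 21), 12 for genotype by time (18 and 23), 16 for age by time (19 and 25) and 95 for aged against young (3 and 21).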
